A study of Mus musculus with 6 samples.

How the data were processed

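RNA was measured by sequencing after translating ribosome affinity purification from the striatum of mice that carried an Oprm1-Cre allele and a Cre-dependent GFP-L10a. Per the labels, the striata of 2 brains, both hemispheres, were pooled for each library and taken 24 h after the last dose, RNA with an integrity number above 8 was used, and libraries were made with the NEBNext Ultra II RNA kit. The sample labels give the genotype as Oprm1Cre/+ and the series description as Oprm1Cre/Cre, and this was not resolved. The groups were morphine and saline, with 3 libraries each. The titles number the libraries within each group, and no label says that a number marks a shared litter, batch or day.

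The values used are those of the authors' comparison table, made of 4 sheets: 18732 genes, the 2383 genes past adjusted p < 0.05, and these split into 2036 with positive and 347 with negative fold changes. Every gene of the smaller sheets had the values of the full sheet. Per the submitters' processing notes, STAR 2.6.1d, DESeq2 1.20.0 and the builds GRCm38 and mm10 were used, with no roles or order given. The read counter, annotation, model formula and any filter are not given in the sources used here. The authors' deposited mean level per gene is a signal made from counts divided by size factors and averaged over the libraries fitted. The authors' deposited log2 fold changes and their SEs are model estimates on the log2 scale. The deposited statistic is a score, the authors' log2 fold change divided by its SE. The authors' deposited p values are two-sided Wald p values with Benjamini-Hochberg adjusted p values. The adjusted p recomputed from the deposited p values over the 17279 genes that have one differed by at most 2.11e-15, and the other 1453 genes all had a mean of at most 10.9. The table does not name the numerator of the fold change or the libraries fitted. Its title holds an unexplained term, RM-out, which may mean that a library was left out, so the number of libraries behind each SE and p is not known. Positive values are read as higher after morphine, because the sheet of positive values is named as that of increases and morphine is the treatment. If the fit ran the other way, every direction would turn.

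Values per library were not analysed here, so the depth per library is unknown, and the authors' SEs are the only measure of precision. The median SE of the 12486 genes with a mean of at least 100 was 0.15. Genes were matched by Ensembl identifier to GENCODE M21 on GRCm38, which gave a symbol for 18726 identifiers and none for 6. Symbols present on more than 1 identifier numbered 13. The comparison of morphine with saline was counted at the authors' adjusted p < 0.05. The share of called genes that were higher was compared with an even split by an exact two-sided binomial test, with an exact 95% interval.

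Before the data were examined, 48 gene lists were fixed, covering opioid genes, striatal and interneuron markers, markers of other cell types, activity and stress genes, receptors, channels, synaptic and signalling genes, and metabolic and housekeeping genes. Lists with at least 3 tested members, 47 in number, were tested against the other genes with cameraPR of limma 3.58.1 in R 4.3.3. The test used the authors' Wald statistic, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, two-sided. An estimated correlation needs values per library and was not computed. The rule for named genes was also fixed then. It takes Oprm1, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 100, and in each list the 2 highest and 2 lowest called members, or the 2 with the smallest p where none was called. Unnamed genes, predicted gene models, clones and pseudogenes were skipped in the 12 highest and lowest. The values of 10 genes that the rule names are not reported here.

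Chosen after the values were seen, proteins were split by a hydropathy rule on the longest coding sequence of each gene. A membrane segment was a window of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.9, and a signal segment a window of 12 residues within the first 40 with a mean of at least 2.2. Genes whose only segment lay in the last 50 residues, families of mitochondrial proteins and genes of the mitochondrial genome were placed in neither class. Processed pseudogenes were matched to measured coding transcripts with blastn 2.17.0. Intervals of medians came from 2000 bootstrap resamples of genes, and they hold no spread between libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used.

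The steps were tested on simulated data. With 200 of 17279 genes changed by 0.5, 1 or 2 on the log2 scale, 29.4%, 90.5% and 99.6% were recovered. At most 5.37% of the simulated calls were false. These shares are not split by mean level and do not give the recovery of genes with a low mean. Nor do they give the share of false calls among the authors' 2383. An empirical null set from the central values of the authors' statistic had a spread of 1.42, and 1083 genes passed with it. Of simulated lists shifted by 1 unit of the statistic and tested as higher 89.6% were called, against 0.265% of the others. These statistics were drawn as independent standard normal values with no shift by protein class. The shares therefore do not give the share of false calls among the authors' lists past the threshold. The hydropathy rule found 99.8% of 500 membrane, 100% of 500 signal and 1.2% of 500 soluble simulated sequences. The simulated segments were made almost only of hydrophobic residues, so these shares do not give the error rate on real proteins. In a list of 54 genes drawn up as tail-anchored proteins, 17 had no predicted segment. Among these were Sgta and Ubqln4, which encode soluble proteins and do not belong in the list. Alternatives changed the threshold, the genes adjusted over, the centring, the gene set, and the statistic and correlation of the list test.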

Results

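The data describe RNA purified with tagged ribosomes from the striatum, the main input nucleus of the basal ganglia, of mice treated with morphine or saline. The mice carried an Oprm1-Cre allele, Cre recombinase tied to the gene of the mu opioid receptor, and a Cre-dependent GFP-L10a, a large-subunit ribosomal protein fused to GFP. RNA bound by the fusion protein was taken from striatal lysate with antibodies against GFP, a method known as translating ribosome affinity purification. There were 2 groups of 3 libraries each, morphine and saline, and each library pooled the striata of 2 brains taken 24 h after the last dose. Morphine was injected under the skin at 20, 40, 60 and then 100 mg/kg, 2 injections a day for 5 days. The values analysed here are the authors' comparison of the groups, which covers 18732 genes. Values per library were not analysed here, so the depth of each library and the spread between libraries are unknown except through the authors' standard errors.

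The comparison asks which transcripts purified with the ribosomes of Oprm1-Cre cells differ a day after repeated morphine. Such a purification can also carry RNA of cells without the tagged ribosome. As lists, markers of glia, glutamate receptor, channel and transporter genes and unfolded protein response genes were higher after morphine than other genes, and proteasome and histone genes were lower. The lists of opioid genes, GABA receptors and other receptors were higher too, but not once the kind of protein was taken into account. Doing so also left the calls of glutamate receptors, potassium channels, and neurotrophin and growth factor genes close to the threshold. The unfolded protein response list kept its call. Of 14 further response targets listed as cytosolic or nuclear proteins 0 passed, but these do not stand for the whole response. Penk and Pdyn, the genes of the enkephalin and dynorphin precursors, were 2.07-fold and 2.08-fold higher by the authors' deposited table, while Oprm1 itself did not pass the threshold. The direction rests on reading a positive fold change as higher after morphine, since the table names no reference group and does not say which of the 6 libraries were fitted.

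In the authors' deposited table, 2383 of 17279 genes with an adjusted p were past 0.05, of which 2036 were higher and 347 lower. Of the called genes, 85.4% were higher (exact 95% interval 84.0 to 86.8). The exact two-sided binomial p against an even split was 8.19e-290, a description of genes that are not independent of each other. Over all 17279 tested genes the share above 0 was 48.3%, and their median log2 fold change was -0.01. An absolute log2 fold change of at least 1 was reached by 497 called genes that were higher and 186 that were lower.

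Among called genes with a mean of at least 100, the 12 highest included markers of glia and choroid plexus. By the authors' deposited table, Ttr, which encodes the thyroid hormone carrier transthyretin, rose by 4.68 on the log2 scale (SE 0.20, 25.6-fold, adjusted p = 2.89e-111) and is annotated as ENSMUSG00000061808 at 20665280 to 20674321 on chromosome 18 of GRCm38. Others of the 12 in the authors' deposited table were C4b, a complement component (2.82, SE 0.35), Mlc1, an astrocyte membrane protein (2.55, SE 0.34), the glutamine transporter gene Slc38a3 (2.54, SE 0.35), Enpp2, which encodes autotaxin (2.48, SE 0.18), and the microglial receptor gene Csf1r (2.47, SE 0.34). The receptor gene Gpr37l1 was 5.64-fold higher in the authors' deposited table. Sparc (2.39, SE 0.31), the glutamate transporter gene Slc1a3 (2.28, SE 0.22) and the homeobox gene Shox2 (2.19, SE 0.27) were also among them in the authors' deposited table. The authors' deposited table gave Tcf7l2, a Wnt pathway transcription factor, 2.42 with an SE of 0.70 (adjusted p = 0.00559), and mt-Co1, a gene of the mitochondrial genome, 2.25 with an SE of 0.43 (adjusted p = 5.86e-06). These SEs were 4.08 and 3.18 times the median of genes with a similar mean.

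Among the 12 lowest called genes with a mean of at least 100, with gene models, clones and pseudogenes passed over, decreases were smaller. By the authors' deposited table, they included Tnnc1, which encodes cardiac troponin C (-1.32, SE 0.36, adjusted p = 0.00307), Tmem54 (-1.17, SE 0.18, adjusted p = 7.12e-09), AK157302 (-0.96, SE 0.27), Bloc1s1 (-0.83, SE 0.25), Fhit (-0.80, SE 0.26) and Lxn (-0.73, SE 0.18). Hist1h1a (-0.73, SE 0.20), Bex3 (-0.69, SE 0.13), Marcksl1 (-0.67, SE 0.16), Acer2 (-0.67, SE 0.19), Polr2k (-0.66, SE 0.18) and Hist1h1e (-0.66, SE 0.17) completed the 12 lowest in the authors' deposited table. Bloc1s1 shares 55.9% of its exon bases with exons of Rdh5, Hist1h1e shares 25.7% with Hist1h2be, and Polr2k has 1 measured pseudogene at least 95% identical to it. To reach these 12 genes, 67 predicted gene models, clones and pseudogenes were passed over, against 1 among the highest. Processed pseudogenes, copies of mRNAs inserted in the genome, made up 171 of the 347 lower genes and 0 of the higher ones, of 894 tested.

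**Figure D1:**
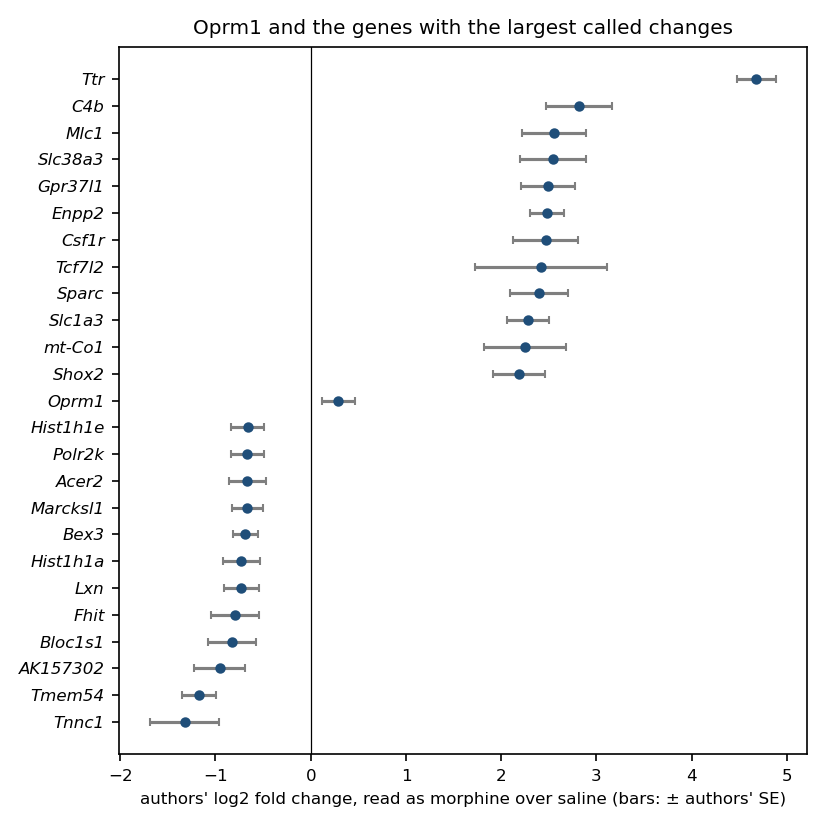
Log2 fold change from the authors' deposited table (x axis, read as morphine over saline) of Oprm1 and of the 12 highest and 12 lowest named genes with a mean of at least 100; points are the estimates and bars the authors' SE. Ttr stands apart at 4.68, and the lowest gene plotted, Tnnc1, is at -1.32.

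The authors' deposited table gave Oprm1 (ENSMUSG00000000766, chromosome 10, 6758506 to 7038198, GRCm38), the gene that the study's Cre line is named for, a log2 fold change of 0.29 (SE 0.18, adjusted p = 0.350). Of 8 opioid receptor and peptide genes, 4 rose and none fell, and 5 passed when adjusted over the list alone. By the authors' deposited table Penk and Pdyn both rose by 1.05 on the log2 scale (SE 0.19 and 0.13), the delta receptor gene Oprd1 by 0.65 (SE 0.15) and the nociceptin receptor gene Oprl1 by 0.46 (SE 0.15). The list was higher than other genes (camera adjusted p = 7.04e-05, limma), but not once the statistic was centred within genes with and without a predicted signal or membrane segment (adjusted p = 0.154, range over 7 alternatives 3.1e-05 to 0.154).

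That centring was chosen after the values were seen, because the called genes differed by the kind of protein they encode. Among 3600 tested coding genes with a predicted signal peptide-like or membrane segment, 1671 were higher and 2 lower, or 46.4% higher, with a median log2 fold change of 0.58. Among 9833 coding genes with no predicted segment, 277 were higher and 139 lower, or 2.82% higher, with a median of -0.06. The gap between the medians was 0.64 on the log2 scale (bootstrap 95% interval 0.63 to 0.66). That interval comes from resampled genes and does not say how far the gap varies between libraries. For the gene lists, this centring was 1 of 7 alternatives, with inter-gene correlations of 0 and 0.05 in place of 0.01, ranks, the log2 fold change as the statistic, genes with a mean of at least 100, and all genes with a p. Where any of them ended or turned a list's call, the range of the adjusted p over the alternatives is given.

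**Figure D2:**
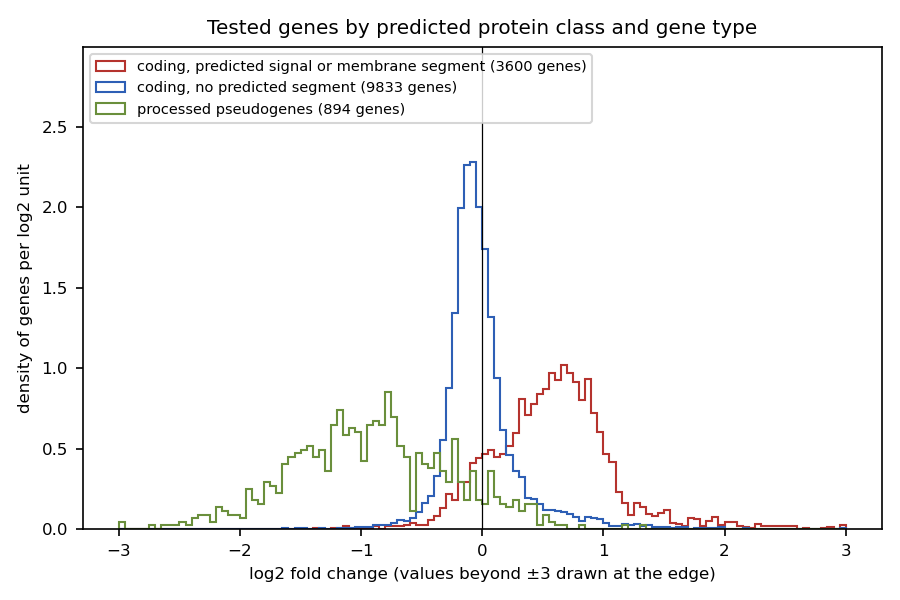
Distribution of the log2 fold change (x axis; density of genes on the y axis) of tested coding genes with a predicted signal or membrane segment, of coding genes without, and of processed pseudogenes. The medians are 0.58, -0.06 and -0.93.

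Markers of striatal projection neurons rose in part. Of 9 direct-pathway markers 5 rose (5 when adjusted over the list alone; camera adjusted p = 0.00034). The authors' deposited table gave the neuropeptide gene Tac1 1.14 (SE 0.17), the dopamine D1 receptor gene Drd1 0.70 (SE 0.13) and Slc35d3 0.63 (SE 0.15). Of 7 indirect-pathway markers 3 rose (4 when adjusted over the list alone; camera adjusted p = 0.00168). The authors' deposited table gave the orphan receptor gene Gpr6 0.64 (SE 0.17) and Grik3 0.62 (SE 0.16). The direct-pathway call was lost in 3 of 7 alternatives (adjusted p 0.000164 to 0.399) and the indirect-pathway call in 2 (adjusted p 0.00097 to 0.386), centring among them. A predicted segment was present in 7 direct-pathway and 6 indirect-pathway members. Of 16 markers of all spiny projection neurons 3 rose (3 when adjusted over the list alone; camera adjusted p = 0.691). The authors' deposited table gave Adcy5, the main striatal adenylyl cyclase, 0.76 (SE 0.12) and Ano3 0.46 (SE 0.15). Striosome markers, which include Oprm1 itself, rose in 6 of 13 (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 4.94e-05, range over 7 alternatives 1.5e-05 to 0.0517). The authors' deposited table gave Sema5b 0.80 (SE 0.16) and the channel gene Asic4 0.69 (SE 0.14). Matrix markers went both ways, 1 higher and 2 lower of 7 (2 and 2 when adjusted over the list alone; camera adjusted p = 0.504). The authors' deposited table gave Epha4 0.61 (SE 0.18), Id4 -0.44 (SE 0.12) and Gda -0.32 (SE 0.12). None of 28 striatal transcription factor genes passed, also when adjusted over the list alone, yet the list was lower than other genes (median -0.09, camera adjusted p = 0.0231). That call was lost in 3 of 7 alternatives (adjusted p 0.00932 to 0.262). The smallest p values in the authors' deposited table belonged to Mef2c (-0.40, SE 0.17) and Dlx5 (-0.28, SE 0.15).

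Interneuron markers rose in part. Of 10 cholinergic markers 6 rose, also when adjusted over the list alone (camera adjusted p = 0.000153, and 0.0182 with centring, range over 7 alternatives 6.3e-05 to 0.0393). The authors' deposited table gave Ecel1 1.08 (SE 0.19), the choline transporter gene Slc5a7 0.78 (SE 0.16) and Slc17a8 0.76 (SE 0.21). Of 16 GABA interneuron markers 5 rose, also when adjusted over the list alone. The authors' deposited table gave Vip 0.79 (SE 0.22), the vesicular GABA transporter gene Slc32a1 0.74 (SE 0.14), Npy 0.58 (SE 0.15) and Sst 0.57 (SE 0.16). That list's call (camera adjusted p = 0.0291) was lost in 4 of 7 alternatives (adjusted p 0.0116 to 0.179), which include an inter-gene correlation of 0.05 (adjusted p = 0.0902).

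Markers of glia and choroid plexus had higher medians than the neuronal lists. Of 17 oligodendrocyte markers 15 rose (17 when adjusted over the list alone; median 1.31, camera adjusted p = 3.09e-23). The authors' deposited table gave the tight junction gene Cldn11 1.97 (SE 0.19), Mag 1.86 (SE 0.21), Cnp 0.73 (SE 0.13) and the myelin gene Mbp 0.65 (SE 0.14). Of 16 astrocyte markers 13 rose (14 when adjusted over the list alone; median 1.43, camera adjusted p = 9.7e-16), among them in the authors' deposited table Slc7a10 at 2.34 (SE 0.64), Slc1a2 at 0.66 (SE 0.17) and Slc4a4 at 0.36 (SE 0.13). Microglial markers rose in 10 of 12 (10 when adjusted over the list alone; median 2.29, camera adjusted p = 1.42e-08). The authors' deposited table gave the fractalkine receptor gene Cx3cr1 2.88 (SE 0.40), C1qb 2.56 (SE 0.72) and Ctss 1.54 (SE 0.44). Oligodendrocyte precursor markers rose in 9 of 11 (9 when adjusted over the list alone; camera adjusted p = 9.36e-07). The authors' deposited table gave Cspg4 1.87 (SE 0.33), Gpr17 1.53 (SE 0.33), Tnr 0.55 (SE 0.16) and Lhfpl3 0.52 (SE 0.16). Of 11 tested ependymal and choroid plexus markers 4 rose (5 when adjusted over the list alone; camera adjusted p = 1.06e-10). Besides Ttr the authors' deposited table gave Folr1 3.16 (SE 0.86), Prlr 2.44 (SE 0.41) and Kl 1.93 (SE 0.25). With centring, the adjusted p of these 5 lists was at most 0.000254.

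Of 13 tested endothelial and pericyte markers 3 rose (5 when adjusted over the list alone), which in the authors' deposited table were Pdgfrb at 1.55 (SE 0.38), Abcc9 at 1.32 (SE 0.45) and Vtn at 1.23 (SE 0.33). That call (camera adjusted p = 0.0357) was lost with an inter-gene correlation of 0.05 (adjusted p = 0.0903), and with centring the direction turned (adjusted p = 0.179, range over 7 alternatives 4.66e-05 to 0.600). Of 5 fibroblast and meningeal markers 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0827). The list passed in 2 of 6 alternatives and turned direction with centring (adjusted p 9.47e-09 to 0.955). The authors' deposited table gave Igf2 2.42 (SE 0.88) and Ptgds 2.05 (SE 0.70). The only measured blood cell marker, Alas2, was at 1.54 (SE 0.92, adjusted p = 0.348) in the authors' deposited table, and with 1 member the list was not tested. Of 15 markers of cortical and thalamic excitatory neurons 4 rose, also when adjusted over the list alone (camera adjusted p = 0.56, median -0.04). Besides Tcf7l2 the authors' deposited table gave Lef1 1.68 (SE 0.41), Slc17a7 0.81 (SE 0.17) and Slc17a6 0.70 (SE 0.21).

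**Figure D3:**
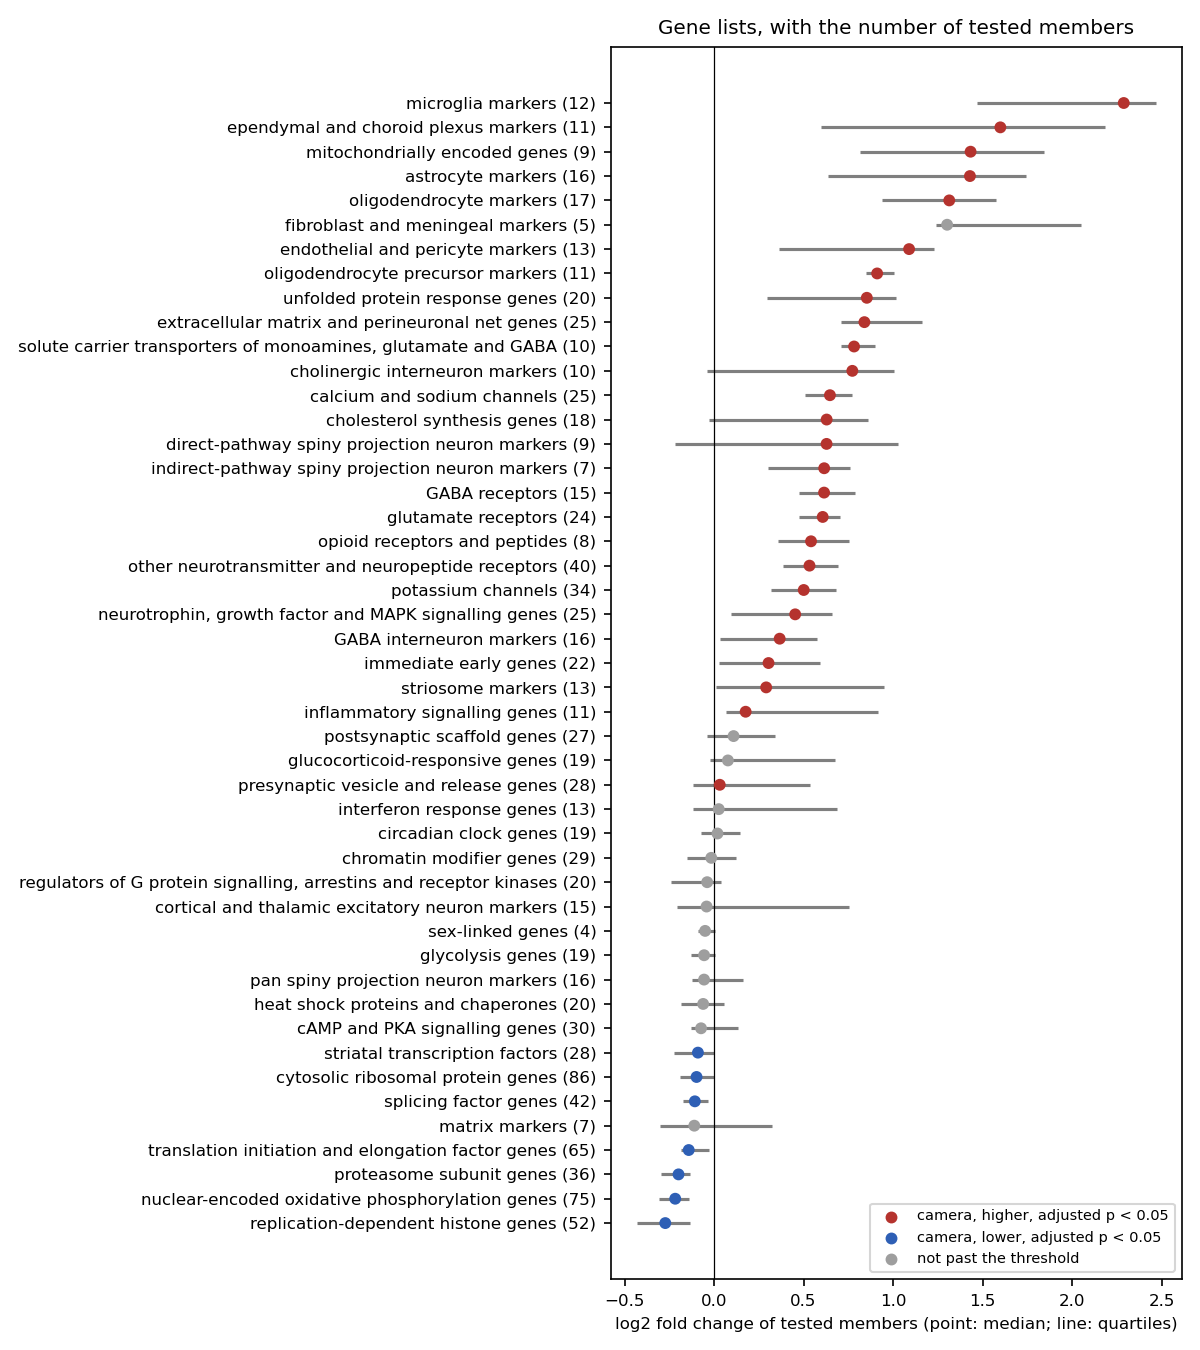
Median log2 fold change (points; lines span the quartiles) of the tested members of each gene list, read as morphine over saline; red and blue lists were higher or lower than other genes by camera at adjusted p < 0.05, grey lists were not. Microglial markers have the highest median, 2.29, and replication-dependent histone genes the lowest, -0.27.

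Of 24 glutamate receptor genes 18 rose (20 when adjusted over the list alone; median 0.61, camera adjusted p = 4.99e-13, and 0.0132 with centring, the highest of 7 alternatives from 6.06e-16). The authors' deposited table gave the NMDA receptor genes Grin2c 1.81 (SE 0.35), Grin1 0.91 (SE 0.16) and Grin2a 0.48 (SE 0.16). Of 15 GABA receptor genes 10 rose (12 when adjusted over the list alone; median 0.61, camera adjusted p = 6.67e-07), among them Gabrd at 0.97 (SE 0.16), Gabra3 at 0.51 (SE 0.17) and Gabra4 at 0.43 (SE 0.13) in the authors' deposited table. Of 40 other transmitter and neuropeptide receptor genes 16 rose (21 when adjusted over the list alone; camera adjusted p = 1.52e-07). The authors' deposited table gave the adrenergic receptor gene Adrb1 and Npy2r 1.01 (SE 0.16 and 0.33), and Cnr1 and Htr1b 0.48 (SE 0.13 and 0.15). With centring the GABA receptor call was lost (adjusted p = 0.317, range over 7 alternatives 8.47e-08 to 0.317), and the direction of the other receptors turned (adjusted p = 0.414, range 4.01e-10 to 0.414). Of 34 potassium channel genes 19 rose (24 when adjusted over the list alone; median 0.50, camera adjusted p = 1.21e-13, and 0.0331 with centring, the highest of 7 alternatives from 5.66e-18). The authors' deposited table gave Kcna5 0.50 (SE 0.14) and Kcnd3 0.43 (SE 0.15). Of 25 calcium and sodium channel genes 19 rose (20 higher and 1 lower when adjusted over the list alone; median 0.65, camera adjusted p = 2.29e-15). The authors' deposited table gave Cacna1i 1.02 (SE 0.13), Cacna1g 1.01 (SE 0.17) and Cacna1e 0.51 (SE 0.16). Of 10 transporters of monoamines, glutamate and GABA 9 rose, also when adjusted over the list alone (camera adjusted p = 3.57e-12). The list shares Slc1a2 and Slc1a3 with the astrocyte markers, which had a median of 1.43. The authors' deposited table gave the GABA transporter gene Slc6a11 1.05 (SE 0.19). All 24 glutamate receptors, 15 GABA receptors, 40 other receptors and 10 transporters, 33 of the 34 potassium channels and 19 of the 25 calcium and sodium channels have a predicted segment.

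Synaptic and signalling lists were mixed. Of 28 presynaptic genes 10 rose and 1 fell (11 and 2 when adjusted over the list alone). The authors' deposited table gave Sv2c 0.98 (SE 0.19), Syt2 0.87 (SE 0.14), Pclo 0.46 (SE 0.15) and the syntaxin gene Stx1a -0.38 (SE 0.13). The presynaptic call (camera adjusted p = 0.0237) was lost in 5 of 7 alternatives (adjusted p 0.0097 to 0.323). Of 27 postsynaptic scaffold genes 6 rose, also when adjusted over the list alone (camera adjusted p = 0.0594). The authors' deposited table gave Nrxn2 0.89 (SE 0.13), Nlgn2 0.67 (SE 0.12) and Lrrtm1 0.44 (SE 0.13). Of 30 cAMP and PKA genes 5 rose, also when adjusted over the list alone (camera adjusted p = 0.707, median -0.07). Besides Adcy5 they included the cyclase genes Adcy9 at 0.96 (SE 0.16), Adcy3 at 0.89 (SE 0.14) and Adcy1 at 0.57 (SE 0.14) in the authors' deposited table. A predicted segment was present in 9 of the 30 cAMP and PKA genes, 8 of the 27 postsynaptic and 12 of the 28 presynaptic genes. All coding genes with such a segment had a median of 0.58. Of 20 regulators of G protein signalling, arrestins and receptor kinases 2 fell and none did when adjusted over the list alone (camera adjusted p = 0.0565), Rgs10 by 0.41 (SE 0.15) and Rgs20 by 0.38 (SE 0.13) in the authors' deposited table. Of 25 tested neurotrophin, growth factor and MAPK genes 9 rose (12 when adjusted over the list alone). The camera adjusted p was 0.000368, and 0.0400 with centring, the highest of 7 alternatives from 6.23e-05. The authors' deposited table gave Ngfr 1.39 (SE 0.51), Fgfr2 1.17 (SE 0.22), Gfra1 0.63 (SE 0.23) and Ntrk2 0.53 (SE 0.15).

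Among genes that respond to activity and stress, 7 of 22 tested immediate early genes rose and 1 fell, also when adjusted over the list alone. The authors' deposited table gave Egr2 1.30 (SE 0.47), Nr4a1 0.95 (SE 0.16), Nr4a3 0.45 (SE 0.14) and Nr4a2 -0.54 (SE 0.16). The call of the immediate early genes (camera adjusted p = 0.02), none of which has a predicted segment, was lost in 3 of 7 alternatives (adjusted p 2.69e-05 to 0.0895). Of 19 tested glucocorticoid-responsive genes 4 rose, also when adjusted over the list alone (camera adjusted p = 0.123). The list passed as higher in 2 of 7 alternatives, centring among them, and turned direction with a mean of at least 100 (adjusted p 0.00431 to 0.936). The authors' deposited table gave the lipid droplet gene Plin4 4.10 (SE 0.66), Gjb6 1.69 (SE 0.50), Pdk4 1.55 (SE 0.52) and the metallothionein gene Mt2 0.65 (SE 0.23). Of 20 unfolded protein response genes 13 rose, also when adjusted over the list alone (median 0.85, camera adjusted p = 2.21e-10). A predicted segment was present in 10 of the 20, and with centring the adjusted p was 4.66e-08 (range over 7 alternatives 3.29e-12 to 3.21e-05). The authors' deposited table gave Creld2 1.33 (SE 0.23), Pdia6 1.12 (SE 0.18), Manf 0.77 (SE 0.18) and Dnajb9 0.69 (SE 0.18). None of 20 heat shock genes passed, also when adjusted over the list alone (camera adjusted p = 0.113), and the smallest p values in the authors' deposited table were those of Hspa2 (-0.29, SE 0.15) and Hspa8 (-0.22, SE 0.12). Of 19 circadian clock genes 1 rose, also when adjusted over the list alone (camera adjusted p = 0.917), Bhlhe40 at 0.46 (SE 0.14) in the authors' deposited table. Of 13 interferon response genes 2 rose (3 when adjusted over the list alone; camera adjusted p = 0.641), H2-D1 at 1.16 (SE 0.25) and B2m at 0.69 (SE 0.24) in the authors' deposited table. Of 11 inflammatory signalling genes 4 rose, also when adjusted over the list alone. The authors' deposited table gave Vcam1 1.35 (SE 0.44), Serpina3n 1.34 (SE 0.39), Ptgs2 0.83 (SE 0.28) and Il6st 2.00-fold higher. The inflammatory call (camera adjusted p = 0.0359) was lost in 3 of 7 alternatives (adjusted p 0.0215 to 0.525).

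Of metabolic and matrix genes, 14 of 25 extracellular matrix genes rose (17 when adjusted over the list alone; camera adjusted p = 4.99e-13). The authors' deposited table gave Timp3 2.04 (SE 0.22) and Lamb1 0.58 (SE 0.15). Of 18 cholesterol synthesis genes 10 rose, also when adjusted over the list alone (camera adjusted p = 1.07e-05, and 0.0162 with centring, range over 7 alternatives 1.54e-06 to 0.0260). The authors' deposited table gave Dhcr7 0.99 (SE 0.20), Sqle 0.67 (SE 0.18) and Srebf2 0.58 (SE 0.13). Of 19 glycolysis genes 3 rose, also when adjusted over the list alone (camera adjusted p = 0.65), the glucose transporter genes Slc2a1 at 1.03 (SE 0.23) and Slc2a3 at 0.72 (SE 0.14) and the astrocyte aldolase gene Aldoc at 0.88 (SE 0.17) in the authors' deposited table. Of 9 mitochondrially encoded genes 4 rose (7 when adjusted over the list alone; camera adjusted p = 9.36e-07). GFP-L10a tags ribosomes of the cytosol, and this RNA is translated by the ribosomes of mitochondria, so binding to the tag is not the likely route. Carry-over beside the tagged ribosomes was not tested. The authors' deposited table gave mt-Nd5 2.11 (SE 0.22), mt-Nd4 1.84 (SE 0.53) and mt-Cytb 1.83 (SE 0.24) beside mt-Co1.

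Lists of respiratory chain, proteasome, histone and translation genes were lower by small amounts. Of 75 nuclear-encoded oxidative phosphorylation genes 10 fell (7 when adjusted over the list alone; median -0.22, camera adjusted p = 5.34e-10). The authors' deposited table gave Ndufs5 -0.52 (SE 0.15), Ndufb3 -0.50 (SE 0.15), Atp5j2 -0.38 (SE 0.14) and Atp5c1 -0.36 (SE 0.13). Of 36 tested proteasome subunit genes 3 fell and none did when adjusted over the list alone (median -0.20, camera adjusted p = 4.92e-06), Psmb2 at -0.44 (SE 0.14), Psmd8 at -0.41 (SE 0.14) and Psmb7 at -0.36 (SE 0.13) in the authors' deposited table. Of 52 tested replication-dependent histone genes 7 fell and 1 rose (8 and 1 when adjusted over the list alone; camera adjusted p = 1.56e-05). Besides the H1 genes above the authors' deposited table gave Hist1h2bc -0.40 (SE 0.14) and Hist1h4n 0.82 (SE 0.27). Of 86 cytosolic ribosomal protein genes 1 fell, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.000574), Rps3a3, itself a processed pseudogene, at -1.36 (SE 0.37) in the authors' deposited table. Of 65 genes listed as translation factors 1 rose and 1 fell (1 and none when adjusted over the list alone; camera adjusted p = 0.000912), Eif2ak3 at 0.80 (SE 0.17) and Eif2s2 at -0.36 (SE 0.13) in the authors' deposited table. The list was drawn by gene symbol, and Eif2ak3 encodes a kinase, not such a factor. None of 42 splicing factor genes passed, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.00598), and Hnrnpab was at -0.29 (SE 0.12) and Hnrnpl at -0.26 (SE 0.13) in the authors' deposited table. The ribosomal call was lost in 2 of 7 alternatives (adjusted p 2.15e-06 to 0.181), and the translation factor (adjusted p 1.8e-05 to 0.0548) and splicing calls (adjusted p 0.000932 to 0.179) in 3 each. The respiratory chain call was lost with centring, which left 3 of its members (adjusted p = 0.262, range over 7 alternatives 1.89e-16 to 0.262). None of 29 tested chromatin modifier genes passed, also when adjusted over the list alone (camera adjusted p = 0.352). The authors' deposited table gave Hdac3 -0.31 (SE 0.13) and Hdac2 -0.26 (SE 0.13). None of 4 sex-linked genes passed, also when adjusted over the list alone (camera adjusted p = 0.641). The authors' deposited table gave Uty -0.10 (SE 0.16) and Kdm5d -0.09 (SE 0.16).

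The median, mean and test differed in sign for 5 lists, those of all spiny projection neurons, matrix, excitatory neurons, cAMP and PKA signalling, and glycolysis. In all, 9 of the 168 named genes share over 20% of their exon bases with exons of another gene, among them Igf2 (64.5%), Mt2 (73.5%), Hnrnpab (29.1%), Slc32a1 (24.9%), Adcy3 (22.1%) and Timp3 (21.3%). A measured processed pseudogene at least 95% identical was present for 7 named genes, Polr2k, Hspa8, Grin2a, Atp5c1, Ndufs5, Ndufb3 and Eif2s2. The SEs of Ptgds and mt-Nd4 were 3.51 and 3.14 times those of genes with a similar mean.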

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

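The tests with an empirical null, within the predicted protein classes, without pseudogenes, without markers of other cell types and over all genes with a p were chosen after the data were seen. No paired analysis was possible because values per library were not analysed here. For the same reason other tests, other normalizations, other pseudocounts, leaving out libraries, an estimated correlation, other splits of the libraries and the structure of the libraries were not run. The count of 2383 called genes became 783 by Bonferroni (743 higher, 40 lower), 1083 with an empirical null (1025 higher, 58 lower) and 260 among coding genes with no predicted segment (199 higher, 61 lower). It stayed between 1751 and 2861 in the other 11 alternatives. The share of higher genes was 48.3% over all tested genes, called or not, and 76.5% to 99.3% in the other 9 alternatives. Past the threshold were 19 lists with the statistic centred within the predicted classes, against 33, and 24 to 35 in the other alternatives. Centring also left out genes in neither class, so the mitochondrially encoded list was not tested there and the respiratory chain list kept 3 members. The cause of these moves was not tested. Lists of other cell types past it numbered 6, and 4 to 7 in the alternatives.

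Some lists turned direction, none of them past the threshold after the turn, and the cause was not tested. With ranks these were markers of all spiny projection neurons (adjusted p = 0.905) and cAMP and PKA genes (adjusted p = 0.503). With the log2 fold change as the statistic they were the same neurons (adjusted p = 0.971), clock genes (adjusted p = 0.918) and cAMP and PKA genes (adjusted p = 0.994). With a mean of at least 100 they were glucocorticoid-responsive and clock genes (adjusted p = 0.936 each). With centring they were markers of all spiny projection neurons (adjusted p = 0.879), endothelium and pericytes (adjusted p = 0.179), fibroblasts (adjusted p = 0.955), sex-linked genes (adjusted p = 0.990), cAMP and PKA genes (adjusted p = 0.780), other receptors (adjusted p = 0.414), chromatin modifiers (adjusted p = 0.780) and interferon genes (adjusted p = 0.884). Of the 168 named genes 73 kept their side of the threshold in every alternative that held them and 95 did not. Of the 47 lists 27 kept theirs, 6 of which turned direction in some alternative, and 20 did not. Among the 20 were 4 that passed only in some alternatives: fibroblast markers, glucocorticoid-responsive genes, postsynaptic genes, and regulators of G protein signalling (lowest adjusted p = 9.47e-09, 0.00431, 0.0331 and 0.0346).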

Other observations

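Of the further lists drawn up for the tests, genes listed as tail-anchored proteins had a median log2 fold change of -0.10 over 54 genes and mitochondrial carriers -0.06 over 46. Of further markers of cytosolic or nuclear proteins with no predicted segment, 7 of 17 rose for astrocytes, 4 of 19 for oligodendrocytes, 0 of 15 for microglia and 2 of 9 for thalamic and habenular neurons at the authors' adjusted p. At the authors' unadjusted p under 0.05 the counts were 9, 7, 2 and 3. Of 14 further unfolded protein response targets listed as cytosolic or nuclear proteins, 0 passed at the authors' adjusted p and 0 at their unadjusted p under 0.05.

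The tests on endoplasmic reticulum ribosomes, on glia and vessel RNA as a source of the membrane and secreted gap, and on that gap as a source of the glial and precursor markers were chosen after the results were seen, as was the look at abundant glial markers. Morphine itself stays open as an explanation of each pattern, untested, since it is what the groups differ in. All intervals in these tests come from resampled genes and hold no spread between libraries.

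Genes of membrane and secreted proteins were higher, with a gap of 0.64 in median log2 fold change to other coding genes. RNA of glia and vessel cells as the whole source is argued against by calcium and sodium channel genes, which lay 0.71 above coding genes with no predicted segment (95% interval 0.58 to 0.83, 25 genes). For transcription by the unfolded protein response, 14 targets listed as cytosolic or nuclear lay 0.00718 above those genes (95% interval -0.04 to 0.10). This argues against the part of the response that drives these targets, Atf5, Cebpb, Sesn2 and Aars among them. That list holds none of the response genes that rose, such as Creld2 and Pdia6, so it cannot decide on what drives those. A difference between the groups in the recovery of ribosomes bound to the endoplasmic reticulum may explain it, since genes with a predicted segment lay 0.66 above listed tail-anchored proteins and carriers, most of which are inserted without such ribosomes (95% interval 0.63 to 0.69, 100 genes). Of the 54 members listed as tail-anchored 17 had no predicted segment, the soluble Sgta and Ubqln4 among them. These 17 cannot separate the route of insertion from the lack of a segment. Such a difference in recovery could be technical or follow from morphine.

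Processed pseudogenes were lower, with a median of -0.93 over 894 genes. Genomic DNA in the libraries is argued against by long noncoding RNA genes of matched mean, at a median of -0.0641 (95% interval -0.10 to -0.03), and low counts by coding genes of matched mean, at 0.26 (95% interval 0.20 to 0.32). Reads of near-identical parent genes given to the copies at a different rate may play a part. Copies at least 98% identical to a measured coding transcript lay 0.40 lower than those under 90% or with no match, a gap of -0.40 (95% interval -0.55 to -0.14, 400 genes). The 401 copies from 90 to 98% identical were lower still, at -1.13 against -0.84, and the parents of the closest copies were at -0.13, so identity does not order the copies.

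Markers of glia were higher, with medians from 0.91 to 2.29 over the glial lists. The membrane and secreted gap as the whole source is argued against by astrocyte, oligodendrocyte and microglia members with a predicted segment, which lay 1.21 above all genes with a segment (95% interval 0.85 to 1.63, 30 genes). For the 11 oligodendrocyte precursor markers, whose 6 members with a segment lay 0.34 above that class, it is argued against by a median of 0.90 above the members' own classes (95% interval 0.29 to 1.03) and an adjusted p of 7.27e-05 with centring (range over 7 alternatives 2.1e-07 to 7.27e-05). RNA of glial cells may account for part of it, since further glial markers of cytosolic or nuclear proteins lay 0.58 above other genes with no segment (95% interval 0.28 to 0.71, 51 genes). Of the 14 with a mean of at least 1000, 3 rose, against 2.82% of all coding genes with no segment. The median of these 14 was -0.01 (95% interval -0.15 to 0.34). Whether their RNA came mainly from glia was not tested. The markers were not matched on mean to the other genes. Coding genes of any class matched on mean to processed pseudogenes lay at 0.26, so how much of the gap goes with mean level is not known. Thalamic tissue in the dissection cannot be told apart from none, since 9 genes at 0.34 leave a wide interval (-0.32 to 1.04). Of these 9 genes 2 rose, against 2.82% of all coding genes with no segment. Of the 15 markers of cortical and thalamic excitatory neurons 4 rose, Tcf7l2 and Lef1 among them, while the median of that list was -0.04.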
